A study of Mus musculus with 10 samples.

How the data were processed

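Total RNA of mouse germinal vesicle oocytes was purified with a Picopure kit, labelled with biotin by a small-sample protocol and hybridised to single-colour arrays, per the labels' protocols. The deposited values are intensity values, 1 linear signal per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version and any chip file settings were not given in the sources used here. In the deposited table the mean of each array's values, after leaving out the lowest and highest 2%, was 150.001 on all 10 arrays, so 1 scaling factor per array had been applied. No detection calls were used here. MAS5 subtracts mismatch probes, which makes dim signals variable, and the scaling assumes that the mean signal is equal between groups.

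Groups and replicate numbers came from the sample titles: 5 wild-type and 5 CTCF-depleted arrays. Of the probe sets without controls, 34945 had 1 gene symbol, 932 several and 9160 none in the platform annotation. Of those with 1 symbol, 34741 were found by gene ID in a RefSeq gene table of assembly GRCm38.p6, used for names and for which genes lie next to each other, and 0 symbols changed. The array files name no genome build, so no coordinates are given.

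The 64 control probe sets were left out of the fit. Signals were transformed as log2(signal + 2.47), the offset being the 25th percentile of all values, which understates changes of dim genes. Probe sets with a mean log2 value under the 40th percentile, a signal of about 5.13, were left out, leaving 27022 probe sets. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets and calls at an adjusted p under 0.05. A gene with 1 symbol was represented by its probe set with the highest mean, giving 13811 genes, and for named genes other probe sets are given where any had the opposite sign. Fold changes are on this log2 scale, depleted over wild type. Single values were compared by two-sided exact permutation tests, whose smallest possible p is 0.00794. Shares carry 95% exact binomial intervals, which give counting error only, because genes and probe sets are not independent.

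The files hold no detection limit, so the highest of 27 Bacillus control probe sets, transcripts that mouse RNA lacks, served as each array's background level, a choice made after seeing the data. Where all arrays of a group lay at or under it, the change is given as at least N-fold: the mean log2 signal of the brighter group against the dimmer group's mean of, per array, the higher of that level and the signal itself.

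The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were all Ctcf probe sets, the 12 largest called rises and 12 largest called falls with 1 symbol (0 clone names skipped in either direction), up to 4 members of each list with the smallest adjusted p, and the Actb and Gapdh controls. Other genes named beside a count or as examples of a list were chosen after their values were seen. The 22 lists, written from general knowledge, covered oocyte growth and zona pellucida, maternal effect genes, meiotic cell cycle, cohesin and CTCF partners, imprinted genes, chromatin regulators, RNA polymerase II, mRNA storage and decay, small RNA pathway, interferon response, p53 and apoptosis, glycolysis, citric acid cycle, heat shock, early embryonic transcripts, ribosomal proteins, mitochondrial ribosome, oxidative phosphorylation and proteasome. They also covered markers of granulosa and cumulus cells, of theca and stroma, and of blood, immune and endothelial cells. A few genes, such as Ago2 and Sdhb, stood in several lists. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 22 lists.

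The alternatives were other offsets and filters, median centring, quantile normalization, other variance models, array weights, the replicate number as a block, the ratio of 3-prime to 5-prime signal as a covariate, other thresholds, the mean over a gene's probe sets and leaving out each array. A filter on mean signal of at least 100 and leaving out depleted replicates 2 and 5 together were added after seeing the data. The fit was tested on simulated data for 27022 probe sets with the real means and spread. Of 100 probe sets changed by a log2 of 0.5 it recovered 33%, and of 100 changed by 1 it recovered 70%. Of its 110 calls 7 were false, and 0 had the wrong sign. Far fewer probe sets were changed in the simulation than the 3406 called in the real data, so these rates need not hold there. Over 13811 simulated genes, the list shifted by 0.3, the proteasome, was called and 0 of 21 others were. The simulated genes varied independently, whereas the measured proteasome genes had an estimated correlation of 0.150 and a mean log2 fold change of 0.074. False calls of lists whose members vary together, and shifts of that smaller size, were therefore not tested.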

Results

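Gene expression was measured in mouse oocytes at the germinal vesicle stage, the fully grown oocyte arrested in prophase of meiosis I, on Affymetrix-type arrays. The series held 5 arrays of wild-type oocytes and 5 arrays of oocytes depleted of CTCF, a zinc finger protein that binds insulators and helps to fold chromosomes into loops. The labels did not say how CTCF was depleted, how many oocytes went into a sample or whether samples came from separate animals, so the p-values measure the spread between these samples, which may be technical. Each array gave a signal for 45101 probe sets, and between 49.4% and 62.9% of probe sets per array lay above the highest of that array's Bacillus control probe sets. Arrays have no read depth, and their number limits the precision. Correlations between arrays of the same group ran from 0.982 to 0.986 and between groups from 0.976 to 0.981, computed across probe sets, which are not independent replicates. No pair of arrays held identical values. The first principal component held 26.2% of the variance and separated the groups, and the second held 12.9%.

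The comparison of depleted with wild-type oocytes asks which transcripts depend on CTCF, and it begins with the depleted transcript itself. Ctcf signal was far lower in depleted oocytes on both of its probe sets, but it stayed above the control level on 4 of the 5 depleted arrays for the dimmer probe set and on 5 for the brighter. On the dimmer probe set the mean signal was 766 ± 74.1 (SD, n = 5) in wild-type and 20.7 ± 22.7 (SD, n = 5) in depleted oocytes, 2.71% of wild type. On the brighter probe set it was 1001 ± 76.0 against 36.3 ± 33.7, or 3.62% of wild type. The log2 fold changes were -5.43 ± 0.34 (SE) and -5.01 ± 0.31 (limma, Benjamini-Hochberg adjusted p = 1.95e-08 and 1.59e-08). No depleted array overlapped the wild-type arrays on either probe set (two-sided exact permutation p = 0.00794, the smallest that this design allows). The residual signal was uneven: depleted replicate 5 read 61.1 and 95.8, and the other depleted arrays reached at most 14.2 and 29.3.

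**Figure D1:**
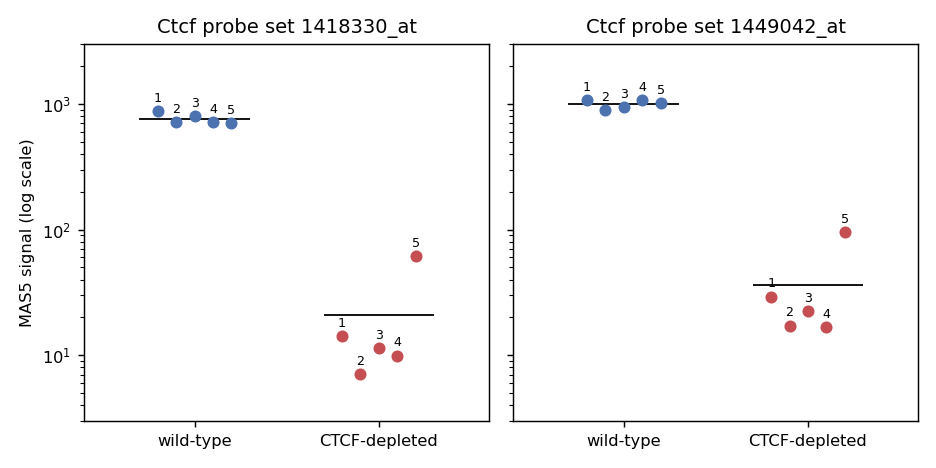
Signal of the 2 Ctcf probe sets (log scale, linear MAS5 units) on each array, numbered by replicate, with group means as lines. All wild-type arrays lie at 699.7 or above, and the highest depleted array, replicate 5, lies at 61.1 and 95.8.

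Apart from Ctcf, the largest rises in depleted oocytes included receptors of immune cells, a glycine-degrading enzyme and chromatin or transcription proteins. Tlr1, a Toll-like receptor for bacterial lipopeptides, was not above the control probe sets on any wild-type array and was at least 19.5-fold higher in depleted oocytes (2.67 ± 3.13 against 156 ± 24.9, SD, n = 5; limma, Benjamini-Hochberg adjusted p = 6.56e-09). Fcgr1, a high-affinity Fc receptor, rose from 7.16 ± 7.40 to 245 ± 47.9, with 1 of the 5 wild-type arrays above the control level, and its other, dimmer probe set rose by a log2 fold change of 0.65. Gldc, the glycine-decarboxylating subunit of the glycine cleavage system, rose 11.8-fold, from 15.5 ± 6.89 to 200.0 ± 26.6. Hmgn3, a nucleosome-binding protein, rose 9.69-fold from 105 ± 21.2 to 1044 ± 235, and its other probe set gave a log2 fold change of 2.89.

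The other largest rises were in Dtd1, a deacylase that clears D-amino acids from tRNA, with a log2 fold change of 2.69 ± 0.11 (SE), and Itgae, an integrin chain, with 2.08 ± 0.14. The Wnt-responsive transcription factor Sp5 rose by 2.65 ± 0.28, the chemokine receptor Cxcr4 by 2.48 ± 0.30 and the Notch-responsive repressor Hes1 by 2.31 ± 0.41. In wild-type oocytes these 3 genes lay above the control level on only 1, 2 and 2 of 5 arrays, so the sizes of their rises depend on the offset. Slc6a12, a betaine and GABA transporter, the transcription factor Sall3 and the glutathione transferase Gstt3 were above it on no wild-type array. They were at least 3.53-fold, 3.10-fold and 2.42-fold higher in depleted oocytes. In limma with Benjamini-Hochberg adjustment, Hes1 had the largest adjusted p of these 12 genes, 0.00117. Only Fcgr1, Hmgn3 and Itgae among them had another tested probe set.

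Among the largest falls were a zinc finger gene, a hyaluronan synthase and a polyamine-degrading enzyme. Zbtb39, a zinc finger protein, fell from 108 ± 6.27 to 7.54 ± 4.60 (SD, n = 5), a log2 fold change of -3.60 ± 0.27 (SE; limma, Benjamini-Hochberg adjusted p = 1.04e-07). Apba2, a neuronal adaptor protein, fell from 42.8 ± 2.69 to 3.02 ± 2.80. Has3, a hyaluronan synthase, fell from 145 ± 4.53 to 20.3 ± 5.34, and Akr1b8, an aldo-keto reductase, from 645 ± 50.7 to 106 ± 44.0. Pigc, which acts in the synthesis of glycosylphosphatidylinositol anchors, fell 4.31-fold from 729 ± 45.0 to 169 ± 30.7. Nr2c1, an orphan nuclear receptor, fell 3.96-fold and Xylb, a xylulokinase, 4.14-fold. Sat1, which acetylates spermidine and spermine, had a log2 fold change of -2.39 ± 0.18, Lect2 of -2.52 ± 0.30, Zfp677 of -2.05 ± 0.24 and Syt12 of -2.02 ± 0.27. The phosphatase gene Ppm1e was above the control level on no depleted array and was at least 3.13-fold lower there. Of the depleted arrays, 2 were above that level for Zbtb39, Lect2 and Syt12, 1 for Apba2 and Zfp677, and 3 for Sat1, so the sizes of these falls depend on the offset.

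**Figure D2:**
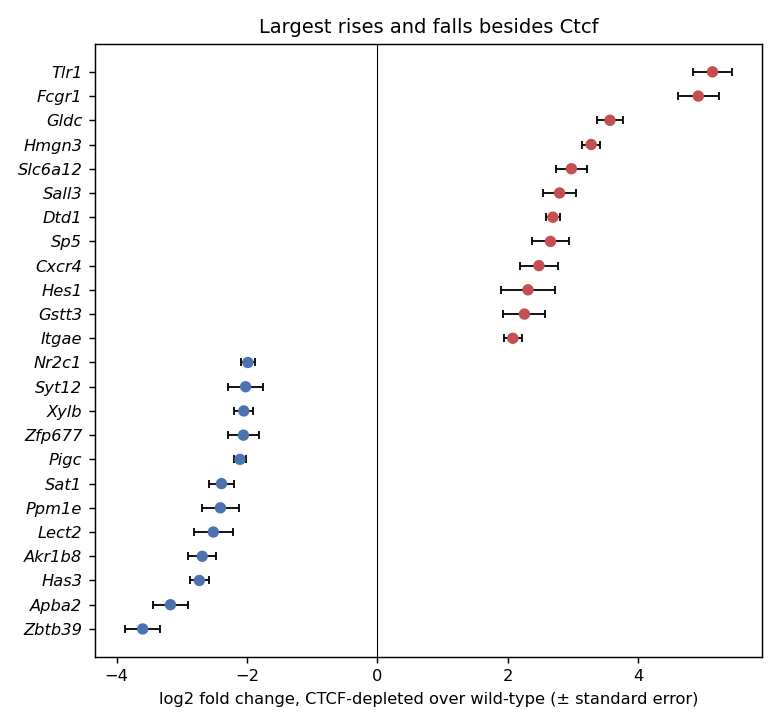
Log2 fold change (CTCF-depleted over wild-type, 5 arrays each) of the 12 largest rises and 12 largest falls besides Ctcf, with standard errors from limma as bars. The falls run from -3.60 for Zbtb39 to -1.99 for Nr2c1. Tlr1, Slc6a12, Sall3, Gstt3 and Ppm1e were at background in 1 group, so their points depend on the offset and only their bounds hold (at least 19.5-fold for Tlr1). Points of genes at background on some arrays of 1 group, such as Fcgr1, Sp5, Apba2 and Zbtb39, also depend on the offset.

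Over all genes, most changes were small, and the larger ones were more often falls. Of 13811 genes tested, 2263 (16.4%) passed limma with Benjamini-Hochberg adjustment, 1003 higher and 1260 lower in depleted oocytes, with a median absolute log2 fold change of 0.43. At least 2-fold changes were seen in 267 genes, 85 higher and 182 lower, so that 68.2% were lower (95% exact binomial interval 62.2 to 73.7). The 1492 called genes under 1.5-fold were divided into 746 higher and 746 lower. The direction of the whole set of calls depended on the scaling of the arrays: 55.7% were lower on the deposited scaling, but with each array centred on its median 1374 genes were higher and 921 lower, or 40.1% lower. Among genes with a mean signal of at least 100, a filter chosen after seeing the data, 857 were higher and 844 lower. Counted as probe sets, 3406 of 27022 were called, 1481 higher and 1925 lower.

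**Figure D3:**
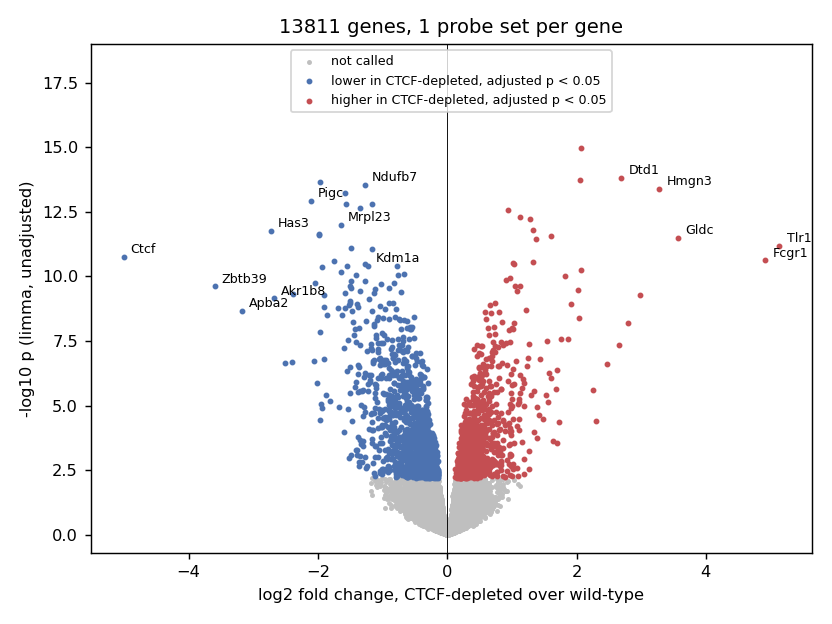
Log2 fold change (x axis, CTCF-depleted over wild-type) against -log10 of limma's unadjusted p (y axis) for 13811 genes, each shown by 1 probe set. Red points are the 1003 genes called higher and blue points the 1260 called lower; Ctcf lies at -5.01 and Hmgn3 at 3.28, and Tlr1, at background in wild type, is drawn at a fitted value for which only the bound of at least 19.5-fold holds.

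Few transcripts that define the growing oocyte were called. Of 26 measured genes of oocyte growth and the zona pellucida, 0 were called higher and 1 lower: Gpr3, the receptor that holds the oocyte in meiotic arrest, had a log2 fold change of -0.18 ± 0.06 (SE), and it was not called when arrays were centred on their medians, where 1 other member was called higher, nor without any 1 of 7 arrays. No member passed when adjusted over the list alone. The egg coat genes Zp1, Zp2 and Zp3 had log2 fold changes of -0.038, -0.045 and -0.018, and the growth factor Gdf9 0.0048, none of them called. Their mean signals in wild type, from 5882 for Zp1 to 9013 for Gdf9, stand against a highest signal per array of 8130 to 10019, so saturation can hide a change in them. Figla and Nobox, transcription factors of the oocyte, had log2 fold changes of 0.24 and 0.096, and the growth factor Bmp6 0.11, and none of these passed. Of 34 maternal effect genes, whose products are needed by the early embryo, 2 rose and 2 fell, and the same numbers passed when adjusted over the list alone, but with single arrays left out 1 to 2 rose and 0 to 2 fell, and 2 and 1 with the covariate, the ratio of 3-prime to 5-prime signal. Basp1 rose 2.02-fold and Khdc3, a member of the subcortical maternal complex, 1.20-fold. Ago2 had a log2 fold change of -0.34 ± 0.10 and Brwd1 of -0.27 ± 0.08, but the other 4 Brwd1 probe sets gave values from -0.13 to 0.22. Under median centring 2 maternal effect genes were higher and 0 lower.

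Genes of the meiotic cell cycle moved both ways: of 45 measured, 3 rose and 4 fell, also when adjusted over the list alone, and 1 rose and 5 fell with the covariate. Ccnb3, a cyclin that acts at meiosis I, fell 1.35-fold from 363 ± 12.7 to 268 ± 17.9 (SD, n = 5), and the kinase Aurkb fell 1.26-fold. Cdc14b, a phosphatase, had a log2 fold change of -0.47 ± 0.09 (SE), but its other probe set gave 0.17. The fourth fall was Ensa, which feeds into phosphatase control at M phase, at -0.36. The centromeric histone Cenpa rose by 0.25 ± 0.06, Ccna2 by 0.21 and Fbxo5, an inhibitor of the anaphase-promoting complex, by 0.19. Mos, the kinase of the metaphase II arrest, had a log2 fold change of 0.042 and was not called.

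Of 33 measured cohesin and condensin genes and partners of CTCF, 3 rose and 5 fell, as they did when adjusted over the list alone, but 3 rose and 2 fell under median centring, 4 and 3 with the covariate, and the falls ran from 2 to 5 with single arrays left out. The alternative cohesin subunits Stag1 and Stag2 rose 1.30-fold and 1.22-fold, and Stag1's other 5 probe sets also gave positive values. Zbtb33, which encodes the methyl-DNA-binding protein Kaiso, rose by a log2 fold change of 0.54 ± 0.09 (SE), but its other probe set gave 0.02. The cohesin subunit Smc1a fell by 0.23 (0.01 on 1 of its other 2 probe sets), the cohesin loader Nipbl by 0.22 (0.022 on 1 of its other 3), and the topoisomerases Top2a and Top2b by 0.20 and 0.46. Nsd1, a histone methyltransferase, had a log2 fold change of -0.26 ± 0.06, with -0.48 and 0.36 on its other probe sets. The cohesin subunits Smc3 and Rad21 had log2 fold changes of 0.074 and -0.11 and were not called, and their other probe sets gave -0.073 for Smc3 and 0.0036 and 0.11 for Rad21.

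Of 39 measured imprinted genes, which are expressed from the allele of a single parent, 2 rose and 5 fell, also when adjusted over the list alone. The falls numbered only 3 without depleted replicate 2, as without depleted replicate 1 or wild-type replicate 2, and 2 rose and 2 fell with the covariate. Meg3, a maternally expressed noncoding RNA, fell from 268 ± 12.4 to 166 ± 7.72 (SD, n = 5), and its other 7 probe sets all gave negative values. Igf2 had a log2 fold change of -0.99 ± 0.29 (SE) at a mean signal of only 26.4 in wild type, with 3 of the 5 depleted arrays above the control level, Dhcr7 of -0.49 ± 0.12, Ppp1r9a of -0.43 ± 0.10 (0.076 on 1 of its other 4 probe sets) and Grb10 of -0.26 ± 0.08. Phlda2 rose 1.77-fold and Slc22a18 1.70-fold. The median log2 fold change of the list was -0.12, also negative under median centring at -0.073 (camera adjusted p = 0.554, and 0.986 with an estimated correlation).

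Most regulators of chromatin and transcription did not pass. Of 69 genes of DNA methylation and chromatin regulation, 2 rose and 4 fell, also when adjusted over the list alone, and 3 rose and 2 fell under median centring and 3 and 3 with the covariate. With single arrays left out, 2 to 3 rose and 2 to 4 fell. Kdm1a, a histone lysine demethylase, fell 2.33-fold from 474 ± 35.7 to 202 ± 22.1 (SD, n = 5), with -1.07 on its other probe set. Carm1, an arginine methyltransferase, rose 1.88-fold and Mbd3, a subunit of a histone deacetylase complex, 1.48-fold. Tet1, a methylcytosine dioxygenase, had a log2 fold change of -0.47 ± 0.13 (SE), Ezh1 of -0.22 ± 0.05 (0.16 on 1 of its other probe sets) and Asf1a of -0.15 ± 0.04. The DNA methyltransferase gene Dnmt1 had -0.022 and Dnmt3l, a germline gene of DNA methylation, had 0.079. Of 63 genes of RNA polymerase II and general transcription, 1 rose and 4 fell (1 and 3 when adjusted over the list alone). Under median centring 1 rose and 2 fell, and with the covariate 0 and 3. When single arrays were left out, 0 to 1 rose and 3 to 5 fell. Tcea1, an elongation factor, rose by 0.19. The log2 fold changes of the falls were -0.45 for Ccnt1 (-0.04 on its other probe set), -0.26 for Ccnh, -0.18 for Med20 and -0.20 for Med14, but the other 4 Med14 probe sets gave values from 0.22 to 0.71.

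RNA regulators also moved both ways. Of 46 genes of maternal mRNA storage and decay, 3 rose and 4 fell (5 and 6 when adjusted over the list alone), and 5 rose and 1 fell under median centring. With single arrays left out, 1 to 4 of them rose and 2 to 5 fell. Upf2, of nonsense-mediated decay, fell by 0.33 ± 0.06 on the log2 scale (SE), the cytoplasmic polyadenylation factor Cpeb1 by 0.18, Papolg by 0.20 and the decapping factor Dcp1a by 0.14. Patl2, an oocyte RNA-binding protein, rose by 0.31 ± 0.06, Pum2 by 0.17 and Pabpc1 by 0.28. Of 26 small RNA pathway genes, 2 rose and 2 fell (2 and 3 when adjusted over the list alone), 2 rose and 1 fell under median centring, and 1 rose and 0 fell with the covariate. Between 0 and 2 rose with single arrays left out. Ago1 fell 2.11-fold but was dim at 39.6 ± 15.6 in wild type, and Ago2, also a maternal effect gene, fell 1.27-fold. Xpo5, which exports small RNA precursors, rose 1.18-fold and Mael 1.19-fold.

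Several heat shock genes rose and none of that list fell. Of 32 genes of heat shock and the unfolded protein response, 7 rose and 0 fell, also when adjusted over the list alone, and no member fell under either other scaling. With single arrays left out, 4 to 7 rose and 0 fell. Hspb1 rose from 265 ± 36.7 to 452 ± 67.3 (SD, n = 5), and Hspa1a 1.95-fold from 188 ± 54.3 to 365 ± 83.0. Hspa1b rose by a log2 fold change of 0.45, Hspa4 by 0.21, Hspd1 by 0.23, Dnajb1 by 0.18 and Dnaja1 by 0.13. The called members were chaperones of the cytosol and mitochondria. The list did not pass as a set (camera adjusted p = 0.324, and 0.986 with an estimated correlation).

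Of 26 genes of the interferon and double-stranded RNA response, 4 rose and 2 fell, also when adjusted over the list alone, with 3 to 4 rising and 1 to 3 falling when single arrays were left out and 3 and 1 with the covariate. Tlr3, a receptor for double-stranded RNA, rose 1.99-fold from 75.3 ± 14.6 to 151 ± 16.7 (SD, n = 5), the RNA-editing enzyme Adar 1.34-fold and Irf1 by a log2 fold change of 0.16. Irf3 rose 1.28-fold on its brightest probe set, but its other probe sets gave 0.1, -1.14 and 0.06, and the mean over them turned its direction. The interferon-induced Oas1b fell 1.74-fold from 203 ± 25.3 to 116 ± 13.8, and Mx1 fell by 0.58 on the log2 scale. Of 36 genes of the p53 pathway and apoptosis, 3 rose and 3 fell (5 and 4 when adjusted over the list alone), and 6 rose and 3 fell under each other scaling. Without depleted replicate 2, 6 rose and 1 fell, without depleted replicate 3, 3 and 5, and with the covariate 5 and 1, and the falls ran from 1 to 5 over all arrays left out in turn. Mdm2, the p53 ubiquitin ligase, rose 1.28-fold, Casp8 1.23-fold and the checkpoint kinase Atr 1.17-fold. Apaf1, the apoptosome scaffold, fell 1.70-fold, and Bbc3 and Chek2 had log2 fold changes of -1.24 ± 0.34 (SE) and -0.64 ± 0.20. Only 1 of the 5 depleted arrays was above the control level for Bbc3 (11.4 against 3.58), so the size of its fall depends on the offset.

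Genes of energy metabolism were called in both directions. Of 26 genes of glycolysis and pyruvate metabolism, 5 rose and 3 fell (6 and 3 when adjusted over the list alone), 7 rose and 0 fell under median centring, and 2 rose and 2 fell with the covariate. With single arrays left out, 2 to 4 rose and 1 to 3 fell. Tpi1 rose 1.41-fold from 755 ± 70.2 to 1060 ± 57.7 (SD, n = 5), Pgam1 by a log2 fold change of 0.40 and Taldo1 by 0.20. Aldoc rose by 1.02, but only 1 of the 5 wild-type arrays was above the control level (5.71 against 13.6), so the size depends on the offset. Pdha1 rose by 0.34 on its brightest probe set, but its other probe set gave -0.35. Pgk1 fell 1.18-fold, Tkt 1.13-fold and Pdk1 by 0.29 on the log2 scale. Gapdh, also on this list, was not among the called members. Its 3-prime, middle and 5-prime control probe sets, left out of the fit, had log2 fold changes of 0.49, 0.62 and 0.68. Of 18 citric acid cycle genes, 1 rose and 2 fell, also when adjusted over the list alone, 1 rose and 1 fell under median centring, 0 and 4 without depleted replicate 2, and 0 and 2 with the covariate and without any 1 of 4 other arrays. Idh1, a member of the list whose cytosolic enzyme lies outside the cycle itself, fell 2.38-fold from 469 ± 36.1 to 202 ± 60.6. Fh1 fell 1.16-fold, and Sdhb rose 1.13-fold. Cs had a log2 fold change of -0.12 and was not called, with 0.061 and -0.0018 on its other probe sets.

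Of 78 genes of oxidative phosphorylation, 3 rose and 10 fell (5 and 10 when adjusted over the list alone), and 5 rose and 7 fell under median centring. With single arrays left out 1 to 4 rose and 8 to 13 fell, and 2 and 7 with the covariate. Ndufb7, a subunit of complex I, fell 2.42-fold from 2243 ± 117 to 926 ± 52.2 (SD, n = 5), and Ndufb10 fell 1.65-fold. The ATP synthase gene Atp5g2 fell 1.39-fold and Ndufv3 1.24-fold. The genes that rose were Ndufs8, Cox6b2 and Sdhb, with log2 fold changes of 0.22 (-0.02 on 1 of its other 5 probe sets), 0.34 and 0.18. Of 76 mitochondrial ribosome genes, 12 rose and 7 fell (16 and 10 when adjusted over the list alone). The balance of these calls moved with the setting: 16 rose and 4 fell under median centring, 6 and 6 with the covariate, 9 and 9 without depleted replicate 2, 8 to 13 and 4 to 9 over all arrays left out in turn, and 6 and 7 without depleted replicates 2 and 5, a choice made after seeing the data. Mrps16 rose 2.17-fold from 555 ± 15.9 to 1212 ± 84.9 and Mrpl16 1.38-fold, while Mrpl23 fell 3.13-fold from 295 ± 21.2 to 92.7 ± 9.30 and Mrps2 2.55-fold. Of 47 cytosolic ribosomal protein genes, 2 rose and 6 fell (2 and 7 when adjusted over the list alone), 3 rose and 3 fell under median centring, and 2 rose and 9 fell without depleted replicate 2. Rps20 fell 1.28-fold, Rps15 1.27-fold and Rpl39l 1.20-fold, and Rpl7 rose 1.16-fold.

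More proteasome genes were called higher than lower. Of 45 measured, 8 rose and 1 fell (9 and 1 when adjusted over the list alone, 3 and 1 with the covariate), and between 4 and 9 rose with single arrays left out. Over the list the median log2 fold change was 0.080. Psmb5, a catalytic subunit, rose 1.32-fold from 826 ± 42.7 to 1095 ± 150 (SD, n = 5) and Psmd12 1.14-fold. Psma1 rose 1.20-fold on its brightest probe set, but its other probe set gave -0.46. Psmd6 fell 1.74-fold from 1471 ± 90.9 to 847 ± 88.5, with -0.86 on its other probe set. This was the only 1 of the 22 lists that passed camera with the preset correlation of 0.01 (adjusted p = 0.0116, adjusted p = 0.986 with an estimated correlation). It no longer passed without depleted replicate 2 (adjusted p = 0.122), without depleted replicate 5 (0.0591), or with the ratio of 3-prime to 5-prime signal as a covariate (0.224).

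**Figure D4:**
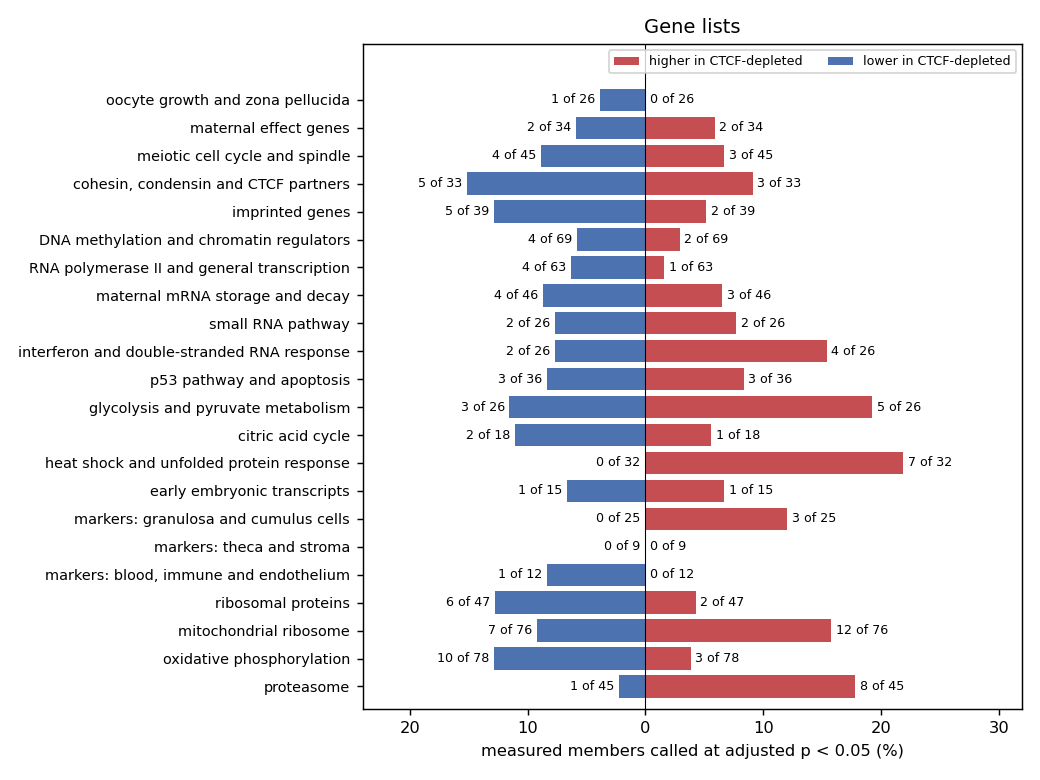
Share of the measured members of each of the 22 gene lists called higher (red, right) or lower (blue, left) in CTCF-depleted oocytes at a limma adjusted p under 0.05, in percent, with counts beside the bars. Heat shock (7 higher, 0 lower) and proteasome (8 higher, 1 lower) lean to the right, and oxidative phosphorylation (3 higher, 10 lower) to the left, by less under median centring (5 and 7).

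As sets, 0 lists passed camera with an estimated correlation, and 0 held more or fewer called genes than expected (Fisher's exact test). The directional test of fry, which does not compare a list with other genes, passed for 4 lists. Imprinted genes, citric acid cycle and blood, immune and endothelial markers passed downward, and glycolysis upward. The citric acid cycle list was not tested without Idh1. The fry test for changes in either direction passed for all 22 lists. The median, the mean and the direction given by camera did not have the same sign for oocyte growth, maternal effect, chromatin, mRNA storage, small RNA, interferon and p53 genes, nor for the granulosa and theca markers.

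Of 15 measured early embryonic transcripts, 1 rose and 1 fell (1 and 2 when adjusted over the list alone), and 2 rose and 1 fell under median centring, and with single arrays left out 1 to 2 rose and 1 to 2 fell. Sox2, a pluripotency factor, rose 2.09-fold from 28.9 ± 3.59 to 63.0 ± 6.61 (SD, n = 5). Eomes had a log2 fold change of -1.39 ± 0.32 (SE) at a wild-type signal of 13.7, and 1 of the 5 depleted arrays was above the control level. Cdx2 and Tcstv3 had log2 fold changes of -0.92 and -0.26 and were not called.

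Markers of other ovarian cells and the control transcripts were measured beside these groups. Of 25 granulosa and cumulus markers, 3 rose and 0 fell (3 and 2 when adjusted over the list alone), with 0 to 2 falling when single arrays were left out and 1 with the covariate. Nr5a2 rose 1.24-fold and Fshr, the receptor of follicle-stimulating hormone, 2.01-fold from 23.2 ± 6.69 to 47.8 ± 5.75 (SD, n = 5). Ptgs2, above the control level on no wild-type array, was at least 1.85-fold higher. The bright marker Inha had signals of 230 in wild type and 147 in depleted oocytes, with a log2 fold change of -0.43 ± 0.29 (SE), and Has2 had -0.96 ± 0.31. Of 9 theca and stroma markers, 0 were called and 0 when adjusted over the list alone, but 1 was called higher under each other scaling, with Nr2f2 at 0.44, Gli1 at 0.41, Col1a2 at -0.62 and Acta2 at -0.30. Of 12 blood, immune and endothelial markers, 0 rose and 1 fell, also when adjusted over the list alone. H2-Aa, a class II histocompatibility chain, fell 2.54-fold from 100.1 ± 22.9 to 37.1 ± 1.89, and Vwf, Pecam1 and Lyz2 had log2 fold changes of -0.62, 0.19 and -0.53.

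The 3-prime, middle and 5-prime Gapdh control probe sets had log2 fold changes of 0.49, 0.62 and 0.68 (two-sided exact permutation p = 0.00794 for each), positive under both other scalings. Those of Actb had 0.05, 0.17 and 0.09 (exact permutation p = 0.817, 0.183 and 0.627). The log2 ratio of 3-prime to 5-prime signal over both genes, a sign of RNA length, was 2.95 ± 0.13 in wild-type and 2.82 ± 0.15 in depleted oocytes (SD, n = 5; exact permutation p = 0.175). For Gapdh alone it was 3.13 ± 0.15 against 2.92 ± 0.13 (exact permutation p = 0.0556).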

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

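Of the tests in this part, only those of other splits of the arrays, of RNA quality and of dim probe sets had their bounds set before the result was seen. The test of dim probe sets used the filter at a mean signal of at least 100, itself chosen after seeing the data. The tests of strain variants, granulosa cells, immune cells and scaling were set after. The strain variant test was run in several forms. It was run at first on the genes changed at least 2-fold alone, then on all called genes with a bound of 50%. A bound of 20% followed and was dropped because it had been chosen after the value was known. The last bound, the 2.5% expected where no probe set changes, was also set after the value was known. The granulosa test first counted a low share of called markers as evidence against these cells and was then divided by size of change. The immune cell test first took the lack of called markers as evidence against such cells, and that reading was dropped.

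Single arrays stood apart from the rest of their group in 7 of 228 groups of 5 arrays, fewer than the 11.4 that chance gives, by the gap to the nearest array over the range of the group, on the log2 scale with the offset (critical value 0.71). On that scale the Ctcf signals of depleted replicate 5 lay just under the critical value, at 0.707 and 0.691, but on the linear scale they gave 0.869 and 0.841, and 13 groups passed it in place of 7. For Pigc the gap of depleted replicate 5 was 0.795 of the range, at 223 against 149 to 162 on the others. For Sp5 depleted replicate 4 gave 0.718 (51.2 against 38.2 to 41.5), and for H2-Aa the same array gave 0.729 (40.4 against 35.6 to 36.9). In wild type, Slc6a12 gave 0.785 for replicate 3, all at background, and Atr gave 0.742 for replicate 1 (440 against 501 to 524). Cs gave 0.878 for replicate 5 (4090 against 3816 to 3848), and Rpl39l gave 0.767 for replicate 4 (2400.4 against 2065 to 2139).

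Many probe sets differed between the groups. A chance division of these arrays is argued against: 1 of 100 splits drawn from the 126 possible, the real one, gave as many calls, with 3406 against at most 2 in the others. The splits cannot exclude a chance difference between the animals, pools or days behind the groups, which the labels do not give. With the ratio of 3-prime to 5-prime signal as a covariate, 73.1% of calls held with the same sign. This argues against RNA length as the whole cause. That ratio rests on Actb and Gapdh alone and differed little between the groups (2.95 and 2.82), so the test says little about other differences in RNA quality. Granulosa and cumulus markers showed no shared 2-fold change, with a median log2 fold change of -0.020 (quartiles -0.30 and 0.17). Markers such as Ptgs2 and Has2 were dim, and the offset understates changes of dim genes, so this does not exclude such cells. Strain variants under single probe sets as the whole cause are argued against in the 781 called genes that have another probe set with a mean signal of at least 20. Of their 1162 other probe sets, 52.3% (95% interval 49.4 to 55.2) moved the same way at an unadjusted limma p under 0.05. The 2.5% used as the bound is the share expected where no probe set changes. It is too low a base here, since 6876 of all 27022 tested probe sets had an unadjusted p under 0.05 in either direction. After adjustment, 401 passed with the same and 18 with the opposite sign. The test bears only on variants under single probe sets. Among genes changed at least 2-fold, 36 of 267 have another probe set of that signal, and 100% (43 of 43) moved the same way. Probe sets of a gene can share sequence, which was not tested, and a part of the calls can still come from variants. Variants stay open for the 1482 called genes with no other probe set of that signal, among them Tlr1, Gldc, Zbtb39 and Has3. None of the 12 largest falls had another tested probe set, and of the 12 largest rises only Fcgr1, Hmgn3 and Itgae did. For Fcgr1 that probe set gave a log2 fold change of 0.65, against 4.92 on the brighter one. Also open are granulosa or cumulus cells, with 12% of markers called, and an effect of CTCF depletion, the labelled difference.

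Tlr1 and Fcgr1, genes of immune cells, were the largest rises. Immune or blood cells in the depleted samples could not be excluded. Of the 12 measured markers 0 were called higher and 1 lower, H2-Aa, but Lyz2 and Cd74, abundant in macrophages and antigen-presenting cells, had mean signals of only 10.3 and 13.1 in wild-type and 5.38 and 10.6 in depleted oocytes, near the control level, and C1qb had 183 and 195. H2-Eb1, a class II gene of antigen-presenting cells chosen here after its value was seen, rose by a log2 fold change of 1.02, and Cxcr4 and Itgae, also genes of immune cells, were among the largest rises.

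Changes of at least 2-fold were mostly falls, 68.2%. The share stayed over 50% under the other scalings, at 58.3% with quantile normalization (95% interval 52.1 to 64.3) and 59.2% with median centring. Among genes with a mean signal of at least 100 it was 64.1% (51.1 to 75.7). These shares argue only weakly against scaling or noise of dim probe sets as the whole cause. Both lower limits lie close to 50%, and the intervals count genes as independent, which they are not. The size of the excess therefore stays open, as does a part played by scaling or dim probe sets. An effect of CTCF depletion, the labelled difference, was not tested apart from these.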

How the results depend on the processing

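The filter at a mean signal of at least 100, the fit without depleted replicates 2 and 5 together, and the rerun of the 2-fold counts were chosen after seeing the data. Ctcf kept its direction and passed in every alternative, with log2 fold changes from -5.42 to -4.67. Genes changed at least 2-fold numbered 148 with the offset at the median, by construction of a larger offset, and 64 with a mean signal of at least 100, where fewer genes were tested. The share of calls that were lower reversed to 40.1% under median centring, which shifted all log2 fold changes by 0.051, and to 49.6% at a mean signal of at least 100; the cause of the second was not tested. At an adjusted p under 0.01, 1821 probe sets and 1268 genes were called, and with a fold of at least 2 added, 398 and 267. Gene lists past the test numbered 0 with the 3-prime to 5-prime covariate, 0 without depleted replicates 2 and 5 (fewer arrays), 0 at a mean signal of at least 100, 0 with an estimated correlation, 4 with directional and 22 with mixed fry, against 1; for the proteasome list the adjusted p of the first 3 was 0.224, 0.264 and 0.141, and the cause was not tested. Leaving out each array in turn gave 2743 to 3315 probe sets, 1847 to 2207 genes, 264 to 286 genes changed at least 2-fold, 54.9% to 58.2% lower calls, and 0 to 1 lists, the proteasome being lost without depleted replicate 2 (adjusted p = 0.122) or 5 (0.0591). With the mean over probe sets, Irf3 reversed to -0.15, Pdha1 to -0.0042 and Psma1 to -0.099, because their other probe sets differ. Of 2610 values of 111 named genes, 2468 stayed on their side of the threshold, 118 lost it, 21 gained it and 3 reversed, and 75 genes were stable throughout; Ago2, Gpr3, Brwd1, Khdc3 and Tkt were lost most often. Replicate numbers gave little sign of pairing: same-numbered deviations correlated at 0.0024 to 0.051, and 2 of 5 arrays in each group correlated best with their own number. With 5 arrays per group this cannot exclude a shared day or batch. The replicate block gave 3581 probe sets and 2354 genes, 2145 of them shared with the 2263. Signal over background limits dim genes, for which only bounds can be given.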

Other observations

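The bound for pairs of neighbouring genes was set before the result was seen, and the tests of unlike names and of gene families were chosen after it.

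Of the genes next to Ctcf, 3 were called. On the side of Ripor1 these were Ripor1, with a log2 fold change of -1.05 ± 0.09 (SE), Atp6v0d1 with -0.55 ± 0.05 and Lrrc36 with -0.59 ± 0.06, while Tppp3 (0.17) and Hsd11b2 (-0.18) were not called. On the other side, Carmil2 (0.20), Acd (-0.083), Pard6a (-0.070), Enkd1 (0.11) and Gfod2 (-0.12) were not called. These genes were chosen for their place and after the values were seen, and no test of the difference between the sides was run.

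Adjacent called genes shared a direction more often than random orders give, and a hypothesis is that neighbouring genes may change in the same direction. With Ctcf left out, 232 adjacent pairs were called in the same direction, against 187 expected and a 95% range of 163 to 212 over 10000 random orders (permutation p = 1e-04, the smallest they can give), and 145 pairs were called in opposite directions against 183 expected. Related genes side by side are argued against as the whole source, since pairs whose symbols differ in their first 3 letters gave 212 against 179 expected (permutation p = 0.0047). Among adjacent pairs changed at least 2-fold were Mtmr6 and Spata13, Plcb4 and Lamp5, and Slc5a12 and Muc15, lower in both members, Pcdhb15 and Pcdhb17, also lower, Slc6a12 and Slc6a13, both higher, and H2-Aa and H2-Eb1, which moved in opposite directions. Overlapping transcripts and shared probe sequence were not tested.

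Among 34 families of at least 30 genes sharing a symbol stem, 0 of 102 tests passed after Benjamini-Hochberg adjustment in limma-based calls, with a smallest adjusted p of 0.829.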
